A study of Mus musculus with 32 samples.

How the data were processed

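RNA from lung and trachea of Car6-/- and wild-type mice was measured on Illumina bead arrays. Per the labels, all mice were C57BL/6 males aged 2 months, and 150 ng of total RNA per sample was labelled with biotin. The 32 arrays cover 28 samples: lung of 6 Car6-/- and 8 wild-type mice and trachea of 6 Car6-/- and 8 wild-type mice. A second array was run for 4 of these samples, and the 2 arrays of a sample were averaged, so that each sample counted once. The labels number the mice within genotype but do not say that a lung and a trachea with 1 number came from 1 animal.

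The authors deposited a table of probe intensity on the linear scale, 1 mean signal per probe and array, neither background-subtracted nor normalized between arrays. Beside each signal, per the file headers, the table holds a detection p-value, the rank of the signal among negative control beads. A further table deposited by the authors holds log2 values that equal the log2 intensity after quantile normalization of the arrays of each tissue separately. That description comes from recomputing the table, in which all but a small share of the differences were 0.005 or smaller. The scanner software, the bead summary and the chip of each array are not given in the sources used here.

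The intensity table was used for every main result. Background was corrected with the normexp model of limma (function nec with the detection p, offset 16), followed by quantile normalization over all 32 arrays and log2. The tools were R 4.3.3 and limma 3.58.1. The array held 25697 probes, of which 23978 carried 1 gene symbol, 0 carried several and 1719 carried none; the named probes covered 16593 symbols. Gene numbers of 23962 named probes were in the RefSeq table, which was used only for names and for the order of genes along chromosomes, since no probe positions were used here. A probe entered a comparison when its detection p was under 0.01 in at least 6 of the samples compared, and the probe with the highest mean represented each symbol. Unnamed probes were tested under their probe number. Where at most 1 sample of a tissue detected a gene named between the tissues, its change is given as at least N-fold, the mean of the brighter group against the mean of, per sample, the higher of its own value and the lowest value of a detected probe.

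Each array detected 11735 to 13139 probes. The median signal per array was 92.4 to 118.3 and the lowest signal 65.7 to 82.7, so that much of the array lay near background. The number of arrays limits the precision.

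Car6-/- and wild-type samples were compared within lung and within trachea, the genotype effect was compared between the tissues in 1 model of all 4 groups, and trachea was compared with lung in wild-type mice. Linear models were fitted with limma (lmFit and eBayes), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Every gene-wise adjusted p in the text comes from limma. Gene lists, 35 in all, were fixed before the data were examined and covered cell types of lung, airway and neighbouring tissues, pathways, carbonic anhydrases and genes near Car6. Lists with at least 5 detected members were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list. The score of a list is the mean log2 intensity of its members in a sample. Exact two-sided permutation tests of these scores over all 3003 splits of the 14 samples of a tissue, and all other exact tests on scores, were added after the data had been seen.

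The genes named follow a rule fixed before the data were examined. Car6 comes first. Then come the 10 called genes with the largest change in each direction, or, where fewer passed, all that passed and up to 5 further genes per direction with the smallest p, named as not past the threshold. Up to 4 members with the smallest p are named for each list discussed in a genotype comparison. For the difference between tissues these are the 5 smallest p in each direction, and for trachea against lung the 5 largest changes in each direction and up to 3 members per cell type list. Detected carbonic anhydrases are always named. Genes outside this rule are marked as chosen after their values were seen.

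The procedure was tested on simulated data with the spread of these samples, in which 100 genes were changed by 0.5 and 100 by 1 on the log2 scale. Of these, 80 and 100 were recovered in the lung design, 33 and 67 in the trachea design, 19 and 76 for the difference between tissues, and 61 and 94 for trachea against lung. Unchanged genes made up 12 of 199 calls in the lung design, 12 of 112 in the trachea design, 22 of 117 for the difference between tissues and 17 of 172 for trachea against lung. A simulated shift of a whole list was called in the lung design (adjusted p = 2.05e-14) but not in the trachea design (adjusted p = 0.361), for the difference between tissues (adjusted p = 0.561) or for trachea against lung (adjusted p = 0.0867). Each gene was drawn independently of the others. The simulation therefore does not show how the list test behaves when the genes of a list vary together.

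Over all genes, sample numbers showed little sign of pairs. The deviations of same-numbered samples correlated at -0.30 to -0.03 between genotypes in lung, -0.19 to 0.55 in trachea and -0.14 to 0.10 between the tissues of 1 genotype. Only 3 of the 14 lung samples correlated best with the trachea sample of their own number. The clock score did follow the number between tissues over all 14 mice (r = 0.84 with genotype means removed). Within the 8 wild-type mice this was less clear (r = 0.45, exact permutation p = 0.277). Shared animals are thus not ruled out. All samples were treated as independent, and the number entered only as an alternative. The alternatives covered background correction, normalization, the authors' log2 table, the probe filter, the choice of probe, second arrays, sample weights, the variance prior, blocks, covariates, leaving out each sample and the fold limit. Further alternatives chosen after the data were seen are named as such where their values are given.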

Results

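The series measured gene expression in lung and trachea of mice that lack Car6, the gene of the secreted carbonic anhydrase VI, and of wild-type mice. Carbonic anhydrases convert carbon dioxide and water to bicarbonate and protons, and the secreted form is found in saliva and milk. Lung was measured in 6 Car6-/- and 8 wild-type mice, and trachea in 6 Car6-/- and 8 wild-type mice. Arrays detected 11735 to 13139 of 25697 probes. Of the 4 second arrays, 3 differed from the first array of their sample by 0.22, 0.23 and 0.26 (root mean square, log2), less than from any other sample. The second array of wild-type trachea 2 differed from its first by 0.37, and from wild-type trachea 6 by 0.34. Values are normalized log2 intensities, and changes are log2 differences of Car6-/- minus wild type unless stated otherwise.

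Car6 itself was not detected in either tissue or genotype. Its only probe (ILMN_1257323) passed the detection threshold on 0 of 32 arrays, with a lowest detection p-value of 0.12. The signal ranged from 79.4 to 97.8 in wild-type lung (n = 8) and from 82.9 to 95.7 in Car6-/- lung (n = 6). In trachea it ranged from 79.9 to 100.9 in wild type (n = 8) and from 82.7 to 96.5 in Car6-/- mice (n = 6). No fold change is given, since all groups lay at background, and the array does not check the genotype labels through this gene.

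The comparison of Car6-/- with wild-type lung addresses what the loss of the enzyme does to gene expression in the distal airways. Oas2, an interferon-induced oligoadenylate synthetase (probe ILMN_2670150), rose by 0.51 ± 0.08 (SE), from 5.72 ± 0.14 (SD, n = 8) to 6.23 ± 0.15 (SD, n = 6). An unnamed probe, ILMN_2958159, rose by 0.55 ± 0.08, from 8.74 ± 0.18 to 9.29 ± 0.11. For both, all 6 Car6-/- samples lay above every wild-type sample (limma adjusted p = 0.036 for each). These were the only genes called of 9417 tested, and 883 had an unadjusted p under 0.05 where 471 are expected by chance. Both calls ended, for instance, with median scaling in place of quantile normalization, where 0 genes were called.

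Among the lung genes with the smallest p that did not pass, Arntl, which encodes the clock activator BMAL1, stood at 1.27 ± 0.25 and the cell cycle inhibitor gene Cdkn1a at 1.06 ± 0.21, each above all wild-type samples in 5 of 6 Car6-/- samples. The tubulin gene Tubb2b (0.41 ± 0.07), Caskin2 (0.43 ± 0.08) and the tendon transcription factor gene Scx (0.43 ± 0.08) were above every wild-type sample in all 6. Rab6b, a small GTPase of Golgi transport, had the lowest estimate of these, -1.82 ± 0.34, with 6.29 ± 0.34 in Car6-/- (n = 6) and 8.11 ± 0.91 in wild-type lung (n = 8). Slco2b1, an organic anion transporter, stood at -0.50 ± 0.08, Arhgef19 at -0.53 ± 0.10, Pdgfrl at -0.51 ± 0.10 and the carbonic anhydrase-related gene Car11 at -0.44 ± 0.09. Adjusted p for these 10 genes was 0.0560 to 0.0858. The number of called genes rose from 2 to 44 without Car6-/- lung 7, 5 without Car6-/- lung 5, and 4 without wild-type lung 1 or 8. It was 1 without wild-type lung 3 and 0 without Car6-/- lung 1, 2, 4 or 6 or wild-type lung 4, 5, 6 or 7.

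Of the 9 gene lists called in lung by camera, 4 lay higher in Car6-/- mice. Immediate early and heat shock genes had a median change of 0.17, with 22 of 24 members higher (adjusted p = 1.95e-04, and adjusted p = 0.130 with an estimated correlation). Its members with the smallest p were the chaperone gene Hsph1 (0.62 ± 0.18), Ppp1r15a (0.20 ± 0.07), Sgk1 (0.27 ± 0.09) and Gadd45g (0.33 ± 0.12). The list score was 8.87 ± 0.14 (SD) in Car6-/- and 8.66 ± 0.08 in wild-type lung, higher than the wild-type mean in 6 of 6 samples. The unfolded protein response list had a median of 0.14 (adjusted p = 0.00193, and adjusted p = 0.373 with an estimated correlation), with the stress transcription factor genes Xbp1 at 0.34 ± 0.09, Ddit3 at 0.39 ± 0.11 and Atf4 at 0.29 ± 0.11, and the chaperone gene Creld2 at 0.26 ± 0.12. Glucocorticoid response genes had a median of 0.30 (adjusted p = 0.0055, and adjusted p = 0.373 with an estimated correlation). Cdkn1a, Map3k6 (0.47 ± 0.12) and Sgk1 were higher there, while the metallothionein gene Mt1 stood at -0.32 ± 0.10. Interferon response genes had a median of 0.06 (adjusted p = 0.0249, and adjusted p = 0.373 with an estimated correlation), with Oas2, Oas1g (0.43 ± 0.10), the antiviral tetherin gene Bst2 (0.54 ± 0.16) and Isg15 (0.36 ± 0.11) leading. Adjusted over the list alone, 2 unfolded protein response genes and 4 interferon genes were higher, 4 glucocorticoid genes higher and 1 lower, and 0 of the heat shock list either way. Over all genes tested, Oas2 alone passed.

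The other 5 called lists lay lower in Car6-/- lung. Cell proliferation genes had a median of -0.18, with 15 of 17 members lower (adjusted p = 0.00124, and adjusted p = 0.189 with an estimated correlation). Named members were the replication licensing genes Mcm2 (-0.38 ± 0.09), Mcm5 (-0.25 ± 0.09) and Mcm6 (-0.18 ± 0.09) and the survivin gene Birc5 (-0.23 ± 0.11). B cell genes had a median of -0.21 (adjusted p = 0.00225, and adjusted p = 0.412 with an estimated correlation), among them the B cell receptor genes Cd79a (-0.36 ± 0.20) and Cd79b (-0.31 ± 0.14), with Fcer2a (-0.31 ± 0.15) and Fcrla (-0.30 ± 0.15). Their score was 5.93, 5.95 and 6.17 in Car6-/- lung 1, 2 and 6, but 6.61, 6.43 and 6.58 in 4, 5 and 7, within the wild-type range of 6.30 to 6.62. MHC class II genes had a median of -0.15 (adjusted p = 0.0054, and adjusted p = 0.373 with an estimated correlation), with H2-Ob at -0.25 ± 0.10, H2-Ab1 at -0.24 ± 0.10, H2-Eb1 at -0.15 ± 0.09 and the invariant chain gene Cd74 at -0.15 ± 0.07. Xenobiotic and redox genes had a median of -0.08 (adjusted p = 0.017, and adjusted p = 0.373 with an estimated correlation). The cytochrome P450 gene Cyp2e1 stood at -0.94 ± 0.37, the alcohol dehydrogenase gene Adh7 at -0.59 ± 0.19, and the glutathione transferase genes Gsta4 at -0.21 ± 0.06 and Gsta2 at -0.35 ± 0.17. Circadian clock genes had a median of -0.38 (adjusted p = 0.0452, and adjusted p = 0.373 with an estimated correlation). Adjusted over the list alone, 4 of its 16 members were higher and 8 lower, and over all genes 0. Beside Arntl these were, by smallest p, Usp2 (-0.51 ± 0.13), the clock activator gene Clock (0.34 ± 0.09) and the repressor gene Nfil3 (0.85 ± 0.24). When adjusted over the list alone, 1 proliferation gene was lower and 0 of the B cell, MHC class II and xenobiotic genes.

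The number of called lists was 15 without Car6-/- lung 2. Without Car6-/- lung 5 and wild-type lung 6, a choice made after the data had been seen, 7 of the 9 calls were kept, and the adjusted p was 0.108 for glucocorticoid response and 0.107 for xenobiotic genes. None of the 9 calls in lung held with an estimated correlation, where 3 lists had an unadjusted p under 0.05. None passed the exact permutation test of list scores (lowest adjusted p = 0.0799), where 7 had an unadjusted p under 0.05. Markers of most lung cell types did not pass in either version of camera. Their preset adjusted p was 0.0506 for endothelium and for ciliated cells, 0.0981 for macrophages and monocytes, 0.125 for adipocytes, 0.251 for neutrophils, 0.371 for alveolar type 1 cells, 0.661 for T and NK cells and 0.664 for alveolar type 2 cells. It was 0.159 for cardiac muscle, 0.209 for airway secretory products, 0.91 for smooth muscle and 0.968 for skeletal muscle and for erythroid cells. It was 0.256 for MHC class I, 0.3 for bicarbonate, chloride and proton transport, 0.325 for collagen, 0.704 for antimicrobial defence, 0.728 for fatty acid oxidation and 0.784 for hypoxia.

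Genes near Car6 on chromosome 4 formed a fixed list of which 41 were tested in lung. As a list they did not move 1 way (median -0.03, adjusted p = 0.125), but single members did. Of the 41, 2 were higher and 6 lower when adjusted over the list alone, and 0 over all genes. Plod1, a collagen lysyl hydroxylase, stood at 0.55 ± 0.11, Miip at -0.57 ± 0.12, Clstn1, which encodes a membrane protein of vesicle transport, at -0.97 ± 0.23 and Agtrap, the angiotensin receptor-associated protein gene, at -0.67 ± 0.16. Of the other carbonic anhydrases in lung, the membrane-bound Car4 of capillary endothelium measured 10.61 ± 0.23 in Car6-/- and 10.64 ± 0.12 in wild type, a change of -0.03 ± 0.09, which turned to 0.06 with median scaling. Car2 stood at 0.18 ± 0.14, Car3 at -0.27 ± 0.68, Car5b at -0.10 ± 0.14, Car13 at -0.03 ± 0.14 and Car14 at -0.07 ± 0.14. None of these passed, and the list of 7 had an adjusted p of 0.251. Leaving out single samples turned the sign of Car3, Car4, Car13 and Car14.

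**Figure D1:**
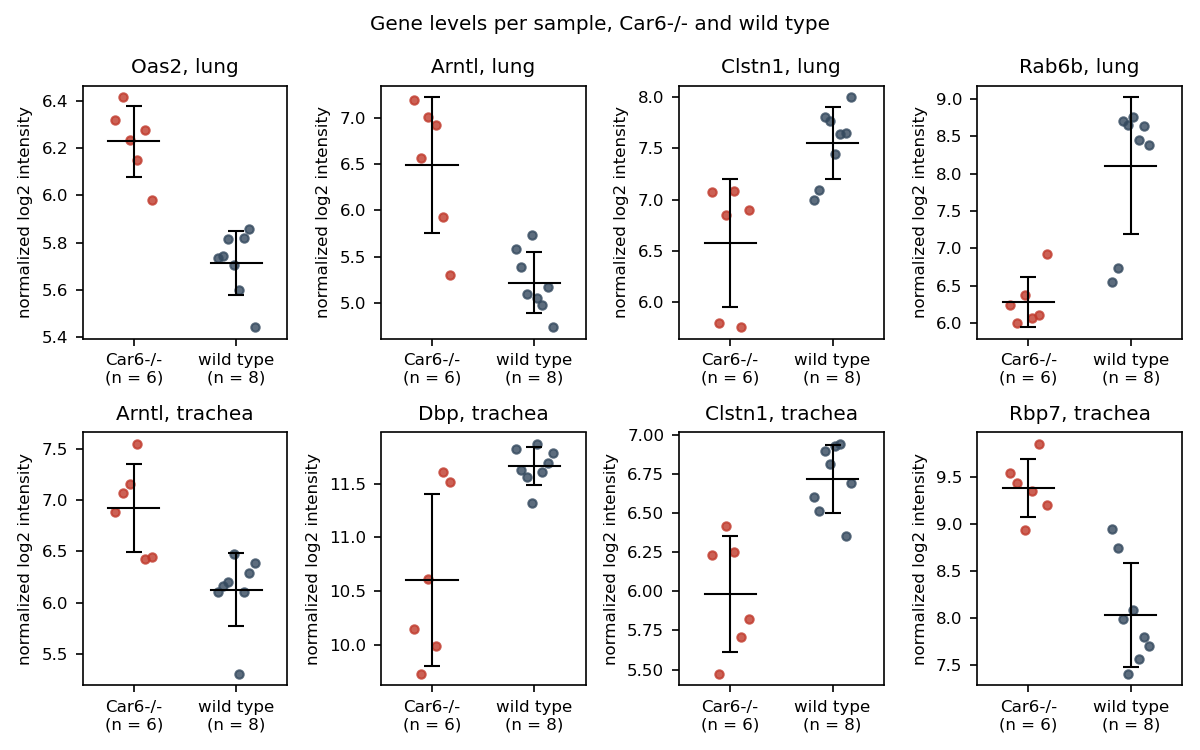
Normalized log2 intensity of named genes per sample (points), with mean and SD (bars), in Car6-/- (n = 6) and wild-type (n = 8) lung and trachea. Oas2 in lung separated the genotypes completely, while wild-type lung 1 and 2 lay at 6.56 and 6.74 for Rab6b, within the range of the Car6-/- samples; of the genes shown only Oas2 in lung passed the threshold.

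The comparison of trachea addresses the same question in the proximal airway. Skeletal muscle genes had a median change of -1.53, with 22 of 24 members lower in Car6-/- trachea (adjusted p = 1.46e-09, and adjusted p = 0.516 with an estimated correlation). The fast-fibre calcium store gene Casq1 stood at -1.85 ± 0.46, the glycolytic enolase gene Eno3 at -1.27 ± 0.34, the creatine kinase gene Ckm at -1.32 ± 0.37 and the glycogen phosphorylase gene Pygm at -1.52 ± 0.43. The muscle score was 10.13 ± 1.48 (SD, n = 6) against 11.53 ± 0.29 (n = 8), with 7.48 in Car6-/- trachea 1, 9.35 in 2, 10.47 in 6 and 11.08 to 11.27 in the other 3. Thyroid and parathyroid genes had a median of -1.34, with 11 of 11 members lower (adjusted p = 1.30e-06, and adjusted p = 0.516 with an estimated correlation). The iodide handling genes Iyd (-3.17 ± 0.99), Dio1 (-2.89 ± 0.82) and Slc5a5 (-1.34 ± 0.41, detected in 2 of 6 Car6-/- samples) and the thyroid transcription factor gene Foxe1 (-2.61 ± 0.78) carried it. Thyroid scores were 4.87, 5.35, 5.21 and 6.42 in Car6-/- trachea 1, 2, 7 and 6, while Car6-/- trachea 4 and 5, at 8.63 and 8.98, lay within the wild-type range of 8.05 to 9.19. In these lists 10 muscle and 7 thyroid genes were lower when adjusted over the list alone, and 0 over all genes.

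Basal and stratified epithelium had a median of -1.23 (adjusted p = 3.58e-05, and adjusted p = 0.558 with an estimated correlation), with the basal keratin genes Krt14 at -1.83 ± 0.78 and Krt5 at -1.34 ± 0.67, the hemidesmosome gene Col17a1 at -1.23 ± 0.60 and Krt6a detected in 1 of 6 Car6-/- and 6 of 8 wild-type samples. Their score was 7.58 ± 1.71 (SD, n = 6) against 8.86 ± 1.36 (n = 8; exact permutation p = 0.162), and without Car6-/- trachea 1, 2 and 6 the median was 0.05 (adjusted p = 0.532). Cartilage genes had a median of -0.62 (adjusted p = 2.63e-05, and adjusted p = 0.516 with an estimated correlation), among them the chondrocyte regulator Sox9 (-1.05 ± 0.32) and the matrix genes Matn1 (-1.18 ± 0.36), Col10a1 (-1.22 ± 0.43) and Comp (-0.64 ± 0.27). Airway secretory and gland products had a median of -0.27 (adjusted p = 0.0387, and adjusted p = 0.558 with an estimated correlation). The mucosal defence gene Dmbt1 stood at -3.34 ± 1.17, the trefoil factor gene Tff2 at -2.16 ± 0.77, Azgp1 at -1.19 ± 0.47 and the goblet cell factor Spdef at -1.13 ± 0.43. The unfolded protein response list had a median of -0.14 (adjusted p = 0.0264, and adjusted p = 0.600 with an estimated correlation), with Chac1 at -1.60 ± 0.46, Dnajc3 at -0.54 ± 0.27, the asparagine synthetase gene Asns at -0.37 ± 0.22 and the disulfide isomerase gene Pdia4 at -0.49 ± 0.31. Without Car6-/- trachea 1, 2 and 6 the adjusted p of this list was 0.478. When adjusted over the list alone, 2 cartilage genes were lower and 0 genes of the other 3 lists, and 0 over all genes.

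Adipocyte genes were higher in Car6-/- trachea, 17 of 17, with a median of 0.97 (adjusted p = 1.48e-08, and adjusted p = 0.516 with an estimated correlation). The adipokine gene Adipoq stood at 0.90 ± 0.26, the lipid carrier gene Fabp4 at 1.09 ± 0.30, the lipase gene Lipe at 1.04 ± 0.30 and the gluconeogenic gene Pck1 at 1.43 ± 0.32 (detected in 2 of 8 wild-type samples). Fatty acid oxidation genes had a median of 0.57 (adjusted p = 5.59e-05, and adjusted p = 0.516 with an estimated correlation), with the lipase inhibitor gene Angptl4 at 1.58 ± 0.29, Slc25a20 at 0.68 ± 0.20, Hadhb at 0.72 ± 0.23 and the pyruvate dehydrogenase kinase gene Pdk4 at 0.71 ± 0.23. Alveolar type 2 genes had a median of 0.85 (adjusted p = 0.0107, and adjusted p = 0.558 with an estimated correlation). The surfactant genes Sftpc (3.32 ± 1.13) and Sftpa1 (2.43 ± 0.75, detected in 3 of 8 wild-type samples) and the lipogenic genes Fasn (1.26 ± 0.40) and Scd1 (0.73 ± 0.22) were its named members. The list score was 10.28 and 10.65 in Car6-/- trachea 1 and 2, 7.65 to 8.66 in the other 4 and at most 8.31 in wild type. Smooth muscle genes had a median of 0.77 (adjusted p = 0.0107, and adjusted p = 0.516 with an estimated correlation), including the contractile genes Acta2 (0.69 ± 0.19), Actg2 (1.03 ± 0.29) and Tagln (0.90 ± 0.23) and their activator Myocd, detected in 5 of 6 Car6-/- and 1 of 8 wild-type samples. Without Car6-/- trachea 1, 2 and 6 the adjusted p was 0.0908 for smooth muscle and 0.849 for alveolar type 2 genes. Endothelial genes had a median of 0.46 (adjusted p = 0.0264, and adjusted p = 0.641 with an estimated correlation), with Esam at 0.59 ± 0.25, Pecam1 at 0.55 ± 0.27, Egfl7 at 0.47 ± 0.26 and the angiopoietin receptor gene Tek at 0.44 ± 0.24. Their score was 9.48 and 9.46 in Car6-/- trachea 1 and 2, 7.99 to 8.55 in the other 4 and 8.05 to 8.60 in wild type. Without Car6-/- trachea 1, 2 and 6, a choice made after the data had been seen, endothelial genes were called lower (median -0.12, adjusted p = 0.0434). Adjusted over the list alone, 12 adipocyte, 8 fatty acid oxidation and 5 alveolar type 2 genes were higher, 6 smooth muscle genes higher and 2 lower, and 0 endothelial genes.

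Among lists of immune and blood genes, 5 were called higher in Car6-/- trachea. B cell genes had a median of 1.22 (adjusted p = 0.0037, and adjusted p = 0.516 with an estimated correlation), with Cd79b at 7.76 ± 2.05 against 6.26 ± 0.35 (SD) and Vpreb3 at 0.64 ± 0.31, while the IgM receptor gene Fcmr and Cd79a were each detected in 5 of 6 Car6-/- and 1 of 8 wild-type samples. Their score was 7.67, 9.61 and 6.85 in Car6-/- trachea 1, 2 and 5, but 5.49, 5.77 and 5.74 in 4, 6 and 7, against 5.34 to 5.72 in wild type. Interferon genes had a median of 0.33, with 27 of 28 members higher (adjusted p = 1.32e-05, and adjusted p = 0.516 with an estimated correlation), among them Ifi27 (0.76 ± 0.18), the interferon signalling factors Stat2 (0.38 ± 0.11) and Irf9 (0.35 ± 0.13) and the chemokine gene Cxcl9 (1.13 ± 0.34). MHC class I genes had a median of 0.42 (adjusted p = 6.53e-05, and adjusted p = 0.516 with an estimated correlation), with H2-Q8 at 0.98 ± 0.27, H2-D1 at 0.56 ± 0.23, the class I transactivator gene Nlrc5 at 0.86 ± 0.28 (detected in 2 of 8 wild-type samples) and the peptide transporter gene Tap2 at 0.42 ± 0.17. MHC class II genes had a median of 0.51 (adjusted p = 0.00368, and adjusted p = 0.558 with an estimated correlation), with the class II transactivator gene Ciita at 0.87 ± 0.40, H2-Eb1 at 0.57 ± 0.26, H2-DMa at 0.60 ± 0.29 and H2-Ob at 0.97 ± 0.50. Erythroid genes had a median of 0.33 (adjusted p = 0.042, and adjusted p = 0.558 with an estimated correlation), with the globin genes Hbb-bt at 0.80 ± 0.28 and Hbb-b2 at 0.93 ± 0.33, the haem synthesis gene Alas2 at 1.01 ± 0.42 and Ube2l6 at 0.54 ± 0.21, a call that held in 4 of the 14 fits with 1 sample left out. Without Car6-/- trachea 1, 2 and 6 the adjusted p was 0.193 for interferon, 0.165 for MHC class I, 0.242 for MHC class II and 0.268 for erythroid genes. Adjusted over the list alone, 2 B cell, 3 interferon and 1 MHC class I gene were higher, and 0 of the MHC class II and erythroid lists.

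**Figure D2:**
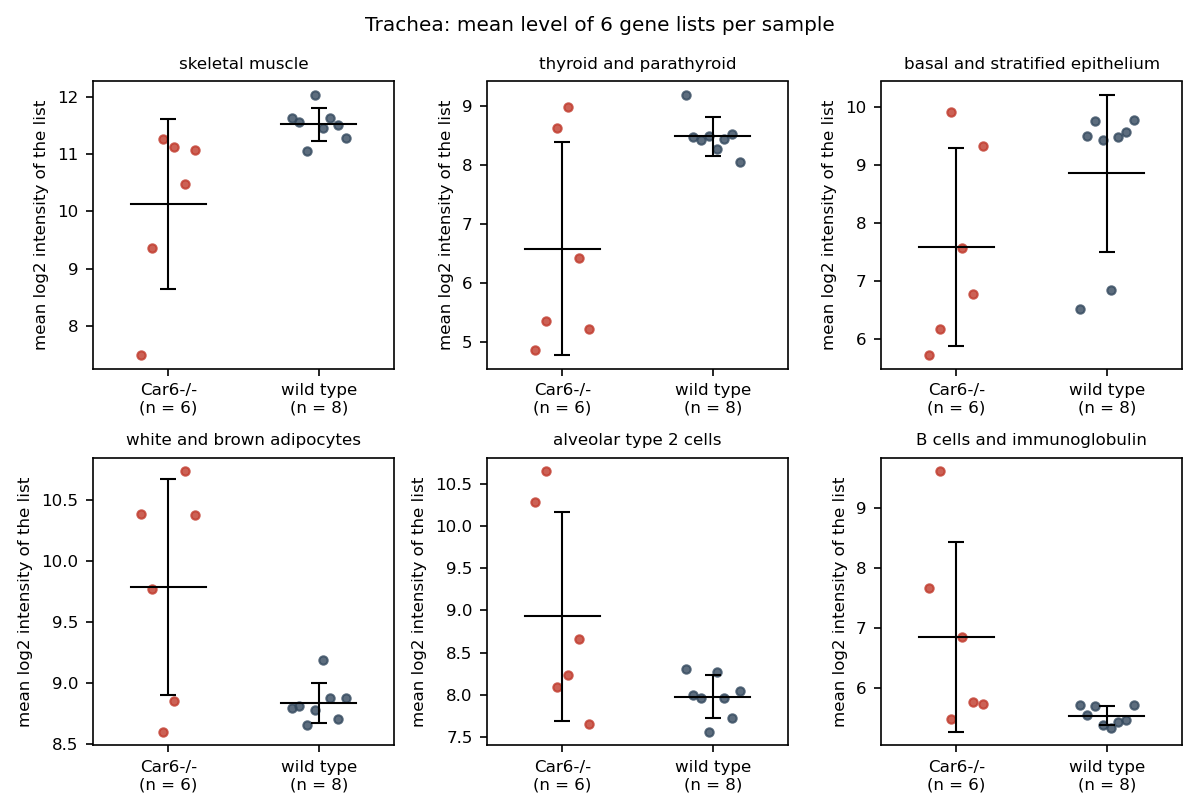
Mean log2 intensity of 6 gene lists in each trachea sample (points), with mean and SD (bars), for Car6-/- (n = 6) and wild-type (n = 8) mice. The Car6-/- samples were spread widely, with skeletal muscle scores from 7.48 to 11.27 against 11.06 to 12.05 in wild type.

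The circadian clock list was called in trachea as in lung, with a median of -0.37 (adjusted p = 0.0279, and adjusted p = 0.516 with an estimated correlation). Dbp, a clock-controlled transcription factor gene, stood at -1.06 ± 0.27, Usp2 at -0.81 ± 0.21, Arntl at 0.80 ± 0.20 and Nfil3 at 1.08 ± 0.25. Of 15 members, 2 were higher and 5 lower when adjusted over the list alone, and 0 over all genes. A clock score, the mean of Arntl, Clock and Nfil3 minus the mean of the detected Dbp, Tef, Nr1d1, Nr1d2, Per and Ciart genes, was formed after the genotype differences of these genes had been seen. It was -0.52 ± 1.00 (SD, n = 6) in Car6-/- and -1.88 ± 0.27 (n = 8) in wild-type lung. In trachea it was -0.20 ± 0.72 (n = 6) and -1.36 ± 0.36 (n = 8). No p-value is given for this difference, since the genes of the score were chosen after their genotype differences had been seen. In lung, Car6-/- mice 1, 2, 4 and 5 scored 0.64, -0.05, -0.28 and -0.03, while mice 6 and 7 scored -1.33 and -2.10. In trachea the same numbers scored 0.43, 0.01, 0.28 and 0.30, against -1.08 and -1.14 for mice 6 and 7.

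**Figure D3:**
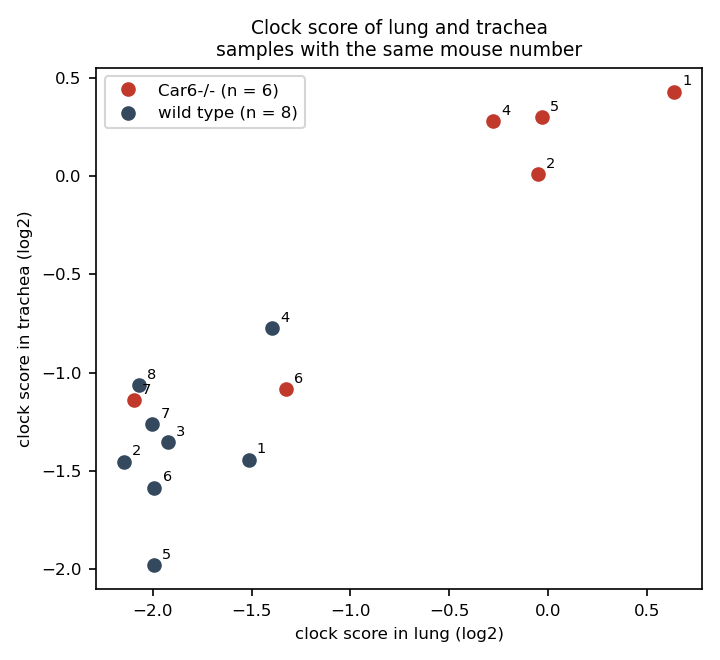
Clock score (log2) of the lung (horizontal axis) and trachea (vertical axis) sample that share a mouse number, for 6 Car6-/- and 8 wild-type mice, labelled by number. Car6-/- mice 1, 2, 4 and 5 lay above every wild-type mouse in both tissues, while mice 6 and 7 lay at -1.33 and -2.10 in lung.

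No single gene was called in trachea by limma (0 of 9736, lowest adjusted p = 0.151), although 1673 had an unadjusted p under 0.05 where 487 are expected by chance. The smallest p belonged to Rbp7, a retinol-binding protein gene that lies near Car6 (1.35 ± 0.24; 9.38 ± 0.31 against 8.03 ± 0.55), followed by Angptl4. The lipid droplet gene Ldah (0.61 ± 0.12), Pdlim7 (0.63 ± 0.13) and Spsb1 (0.57 ± 0.12) were also higher than the wild-type mean in 6 of 6 Car6-/- samples. Tcea3 (-1.20 ± 0.23), Clstn1 (-0.73 ± 0.16), Art5 (-1.31 ± 0.30) and the muscle channel gene Tmem38a (-1.42 ± 0.32) were lower in 6 of 6, and the citrullinating enzyme gene Padi2 was detected in 1 of 6 Car6-/- and 6 of 8 wild-type samples. The count was 693 without Car6-/- trachea 4 and 1 without Car6-/- trachea 5 or wild-type trachea 1, and 1 model of all 4 groups with a shared spread gave 1126. The number of called lists was 10 without Car6-/- trachea 1. None of the 17 list calls held with an estimated correlation (1 unadjusted p under 0.05) or in the exact permutation test of scores, where 13 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.0583 for skeletal muscle.

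Lists that camera did not call in trachea included macrophages and monocytes (adjusted p = 0.0861), tuft cells (0.0911), mast cells and eosinophils (0.147), T and NK cells (0.155), immediate early and heat shock genes (0.273), hypoxia and glucocorticoid response (0.31 each), cardiac muscle (0.369), cell proliferation (0.371), ciliated cells (0.376), neutrophils (0.4) and collagen (0.434). Antimicrobial defence and carbonic anhydrases had an adjusted p of 0.486, xenobiotic metabolism 0.52, and alveolar type 1 cells and bicarbonate transport 0.946. The cardiac muscle score was 12.10 in Car6-/- trachea 1 and 9.74 to 10.21 in wild type. Among carbonic anhydrases in trachea the mitochondrial Car5b stood at 0.61 ± 0.18 and was the only one past the threshold when adjusted over the list alone (0 over all genes). Car4 stood at 0.96 ± 0.38, Car3 at 0.36 ± 0.19, Car12 at -0.77 ± 0.35, Car13 at -0.44 ± 0.43, Car11 at 0.13 ± 0.20, Car2 at -0.11 ± 0.23 and Car14 at 0.03 ± 0.19, the last 2 with a sign that turned when single samples were left out.

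Genes near Car6 again did not move as a list in trachea (median 0.05, adjusted p = 0.291), while 3 were higher and 8 lower when adjusted over the list alone and 0 over all genes. Rbp7 and Clstn1 were described above, Spsb1 stood at 0.57 ± 0.12 and Tnfrsf9, a costimulatory receptor gene, at -1.05 ± 0.27 (detected in 2 of 6 Car6-/- samples). A window of 100 protein-coding genes on each side of Car6 was chosen after these values had been seen. Within it, 4 of 77 genes detected in both tissues (5.19%) had an unadjusted p under 0.05 with the same direction in lung and trachea, compared with 121 of 8066 elsewhere (a ratio of shares of 3.46). The 4 genes were Agtrap, Fbxo44 and Clstn1, lower in both tissues, and Rbp7, higher in both. Elsewhere in the genome, 239 of 17167 windows of this size had as high a share, up to 8.11%.

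**Figure D4:**
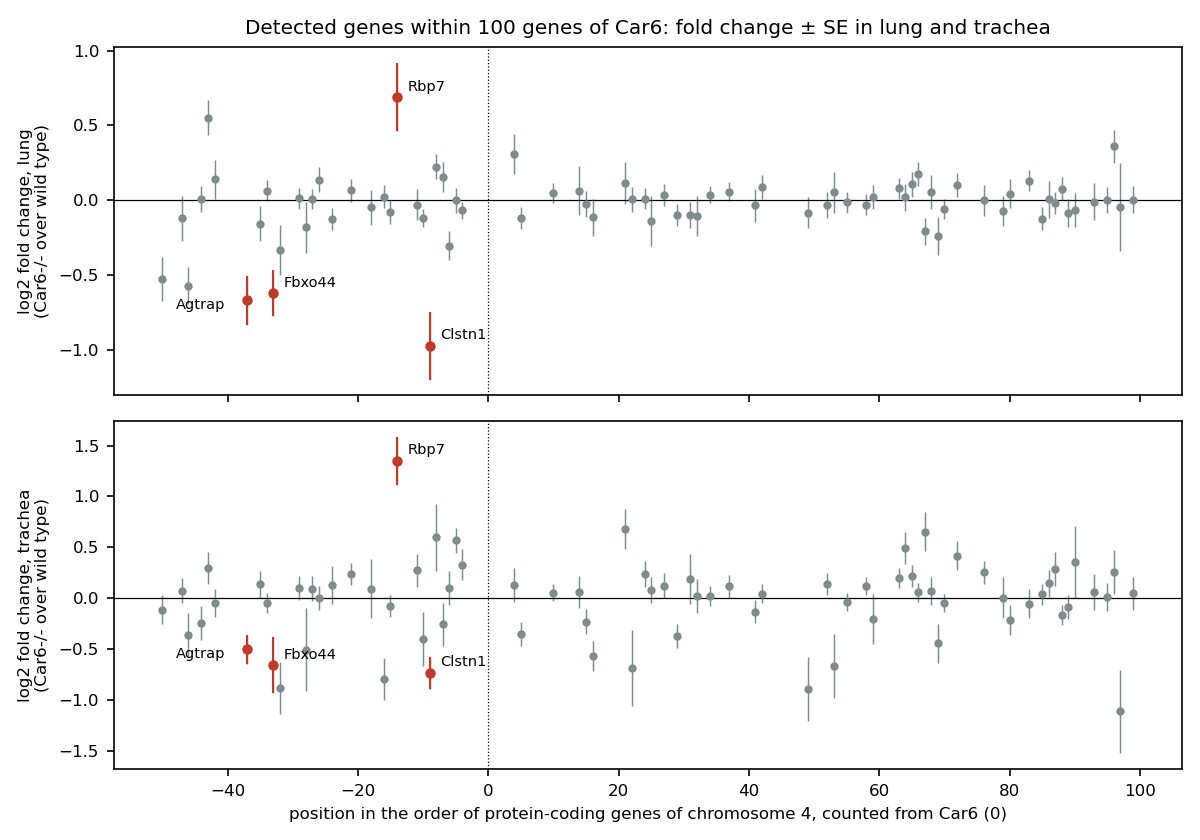
Log2 fold change (Car6-/- over wild type) ± SE of genes detected in both tissues, in lung (top) and trachea (bottom), by position in the order of protein-coding genes of chromosome 4 counted from Car6. The 4 red genes, all on 1 side of Car6, had an unadjusted p under 0.05 and the same direction in both tissues.

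Whether the genotype effect differs between trachea and lung was tested as an interaction over all 28 samples. Effects in trachea exceeded those in lung most clearly for adipocyte genes, with a median difference of 1.07 and 18 of 18 members higher (adjusted p = 6.40e-10), B cell genes (1.12, adjusted p = 2.79e-07), MHC class II genes (0.72, adjusted p = 9.92e-05), fatty acid oxidation genes (0.58, adjusted p = 2.37e-04) and alveolar type 2 genes (1.01, adjusted p = 6.20e-04). With an estimated correlation each of these had an adjusted p of 0.492. MHC class I (0.37, adjusted p = 8.49e-04), smooth muscle (0.66, adjusted p = 0.00455) and macrophage genes (0.33, adjusted p = 0.00498) followed, each with adjusted p = 0.492 with an estimated correlation. Interferon genes differed by 0.23 (adjusted p = 0.00312, and adjusted p = 0.522 with an estimated correlation). The effect was more negative in trachea for skeletal muscle (-1.68, adjusted p = 3.25e-08) and the unfolded protein response (-0.33, adjusted p = 1.53e-04). Thyroid (-1.34, adjusted p = 7.92e-07), cartilage (-0.62, adjusted p = 1.66e-05) and basal epithelium (-1.28, adjusted p = 1.77e-05) were also called, but only 3 of 11, 4 of 15 and 1 of 19 members were detected in lung, so these values repeat the change in trachea and do not compare the tissues. These 5 also had an adjusted p of 0.492 with an estimated correlation. Over genes detected in both tissues, a choice made after the data had been seen, the other 11 lists kept their calls (0 with an estimated correlation), with a median of -1.20 for skeletal muscle. Adjusted over the list alone, 15 adipocyte, 8 B cell, 6 smooth muscle and 4 fatty acid oxidation genes and 1 interferon gene differed upward, and 7 muscle, 5 thyroid and 3 cartilage genes and 1 unfolded protein response gene downward. Only 6 of 13 B cell and 12 of 18 adipocyte genes were detected in both tissues. Part of these 2 counts therefore repeats a change in 1 tissue and does not compare the tissues.

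No gene was called for this difference by limma (0 of 10532, lowest adjusted p = 0.178), and 1446 had an unadjusted p under 0.05 where 527 are expected by chance. The smallest p in the upward direction belonged to Smoc1 (1.44 ± 0.33), Tcte3 (0.73 ± 0.17), Aatk (1.16 ± 0.27), the adipocyte master regulator Pparg (1.57 ± 0.37) and the fatty acid receptor gene Ffar4 (1.23 ± 0.29). In the downward direction they were Exoc3l4 (-0.86 ± 0.18), Tmc7 (-1.23 ± 0.27), the phospholipid transporter gene Abcb4 (-1.53 ± 0.36, undetected in lung), Tcea3 (-1.07 ± 0.26) and Slc25a29 (-1.12 ± 0.27). The value of Abcb4 therefore repeats its change in trachea and does not compare the tissues. The circadian clock list was not called for a difference between the tissues (median -0.08, adjusted p = 0.315), nor were genes near Car6 (0.09, adjusted p = 0.805). Weighting the arrays raised the count of called genes from 0 to 73.

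Trachea and lung of wild-type mice (n = 8 each) were compared to describe the tissues themselves. Changes in this comparison are trachea minus lung. Skeletal muscle genes were higher in trachea, with a median of 6.04 (adjusted p = 2.68e-13, and adjusted p = 0.0667 with an estimated correlation), with Mybpc2 at 5.88 ± 0.20 (detected in 2 of 8 lung samples) and the myosin genes Myh1 and Myh4, each detected in 1 of 8 lung samples, at least 75.2-fold and 81.7-fold higher. Thyroid genes had a median of 4.64 (adjusted p = 8.08e-05, and adjusted p = 0.139 with an estimated correlation), with Iyd at 4.64 ± 0.20 and with Dio1 and Foxe1, undetected in lung, at least 22.6-fold and 19.6-fold higher. Basal epithelium had a median of 4.13 and 18 of 18 members higher (adjusted p = 3.63e-08, and adjusted p = 0.209 with an estimated correlation). Krt15 stood at 6.90 ± 0.20 (detected in 2 of 8 lung samples), the glycerol channel gene Aqp3, detected in 1 of 8, was at least 21.9-fold higher, and the basal cell factor Trp63, undetected in lung, was at least 10.3-fold higher. Cartilage genes had a median of 3.07 (adjusted p = 7.64e-07, and adjusted p = 0.225 with an estimated correlation), with Cytl1 at 4.75 ± 0.23, Col10a1 at least 27.5-fold higher and Matn4 at -3.06 ± 0.15. Airway secretory products had a median of 2.36 (adjusted p = 0.00124, and adjusted p = 0.225 with an estimated correlation), with Dmbt1, detected in 1 of 8 lung samples, at least 195-fold higher, the lactoferrin gene Ltf at 5.05 ± 0.44 and Chad at 3.05 ± 0.24.

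Another 5 lists were higher in trachea. Adipocyte genes had a median of 1.66 (adjusted p = 5.32e-06, and adjusted p = 0.139 with an estimated correlation), with the brown fat gene Cidea at 4.87 ± 0.23 and Thrsp at 4.32 ± 0.29, while the fatty acid transporter gene Cd36 was undetected in trachea and at least 1.86-fold lower. Fatty acid oxidation had a median of 1.25 (adjusted p = 2.22e-06, and adjusted p = 0.134 with an estimated correlation), mast cells and eosinophils 1.51 (adjusted p = 0.0020, and adjusted p = 0.139 with an estimated correlation) and cell proliferation 0.70 (adjusted p = 0.0364, and adjusted p = 0.717 with an estimated correlation). Hypoxia and glycolysis genes had a median of 0.65, and this call held with an estimated correlation (adjusted p = 7.02e-05, and adjusted p = 0.0459 with an estimated correlation).

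Lower in trachea were 8 lists. Alveolar type 2 genes had a median of -4.40 (adjusted p = 2.94e-08, and adjusted p = 0.0459 with an estimated correlation). The surfactant gene Sftpb was undetected in trachea and at least 234-fold lower, the lamellar body gene Lamp3 was at least 20.4-fold lower, and the complement gene Hc, detected in 1 of 8 trachea samples, was at least 46.3-fold lower. Alveolar type 1 genes had a median of -2.50 (adjusted p = 7.32e-05, and adjusted p = 0.0219 with an estimated correlation), with Cav1 at -2.25 ± 0.07, Emp2 at -2.78 ± 0.12 and Clic5 at -2.98 ± 0.16. Endothelial genes had a median of -2.95 and 12 of 12 members lower (adjusted p = 3.63e-08, and adjusted p = 0.0667 with an estimated correlation), among them the adhesion gene Cdh5 (-3.62 ± 0.10), the von Willebrand factor gene Vwf (-3.50 ± 0.10) and Esam (-3.06 ± 0.09). B cell genes had a median of -1.23 (adjusted p = 7.17e-06, and adjusted p = 0.0667 with an estimated correlation), MHC class II genes -1.28 (adjusted p = 7.02e-05, and adjusted p = 0.185 with an estimated correlation) and MHC class I genes -1.03 (adjusted p = 4.28e-04, and adjusted p = 0.194 with an estimated correlation). Interferon genes had a median of -0.66 (adjusted p = 0.00291, and adjusted p = 0.368 with an estimated correlation) and bicarbonate, chloride and proton transport -1.10 (adjusted p = 0.0105, and adjusted p = 0.0667 with an estimated correlation).

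The largest fitted changes belonged to members of such lists and to related genes. Higher in trachea were the muscle genes Mylpf (8.34 ± 0.38) and Tnnc2 (8.31 ± 0.51), each detected in 3 of 8 lung samples, Dmbt1, the gland product Dcpp1 (8.08 ± 0.45, detected in 2 of 8) and the thyroglobulin gene Tg (7.91 ± 0.63). Lower were Sftpb, Sftpc (-8.06 ± 0.28), Sftpa1 (-7.53 ± 0.16, detected in 3 of 8 trachea samples), the lung chemokine gene Cxcl15 (-6.84 ± 0.31) and the phosphate transporter gene Slc34a2, detected in 1 of 8 trachea samples and at least 98.3-fold lower. Carbonic anhydrases split by tissue, all 8 past the threshold. Car3 (4.58 ± 0.43), Car13 (3.30 ± 0.26), Car5b (1.15 ± 0.13) and Car11 (0.51 ± 0.09) were higher in trachea, as was Car12, undetected in lung and at least 1.76-fold higher. Car4 (-4.25 ± 0.11), Car2 (-1.16 ± 0.20) and Car14 (-0.53 ± 0.15) were lower, and the list as a whole was not called (adjusted p = 0.351). In all, limma called 6845 of 10019 genes, 2986 higher and 3859 lower in trachea, of which 1148 and 1171 changed at least 2-fold.

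Members of lists that were not called in this comparison also differed. In trachea the ciliated cell gene Mlf1 stood at 2.00 ± 0.17, Ccdc113 at -1.11 ± 0.13 and Dynlrb2 at -0.77 ± 0.14 (list adjusted p = 0.372). Cardiac muscle genes went both ways, 7 of 14 called higher and 6 lower. The higher ones included Ttn at 4.59 ± 0.34, Hrc at 4.19 ± 0.34 and Tcap at 4.04 ± 0.34 (list adjusted p = 0.365). Smooth muscle genes went both ways, with Des at 2.10 ± 0.10, Hhip at -1.33 ± 0.12 (detected in 2 of 8 trachea samples) and Mylk at -1.68 ± 0.16 (list adjusted p = 0.33). The tuft cell genes Gng13 and Avil were undetected in lung and at least 2.52-fold and 1.26-fold higher in trachea, while Alox5ap stood at -1.44 ± 0.10 (list adjusted p = 0.832). Among macrophage genes, Chil3, a marker of alveolar macrophages, stood at -6.78 ± 0.20, Ly6c1 at -1.55 ± 0.13 and the tissue macrophage gene Folr2 at 1.94 ± 0.12 (list adjusted p = 0.635).

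**Figure D5:**
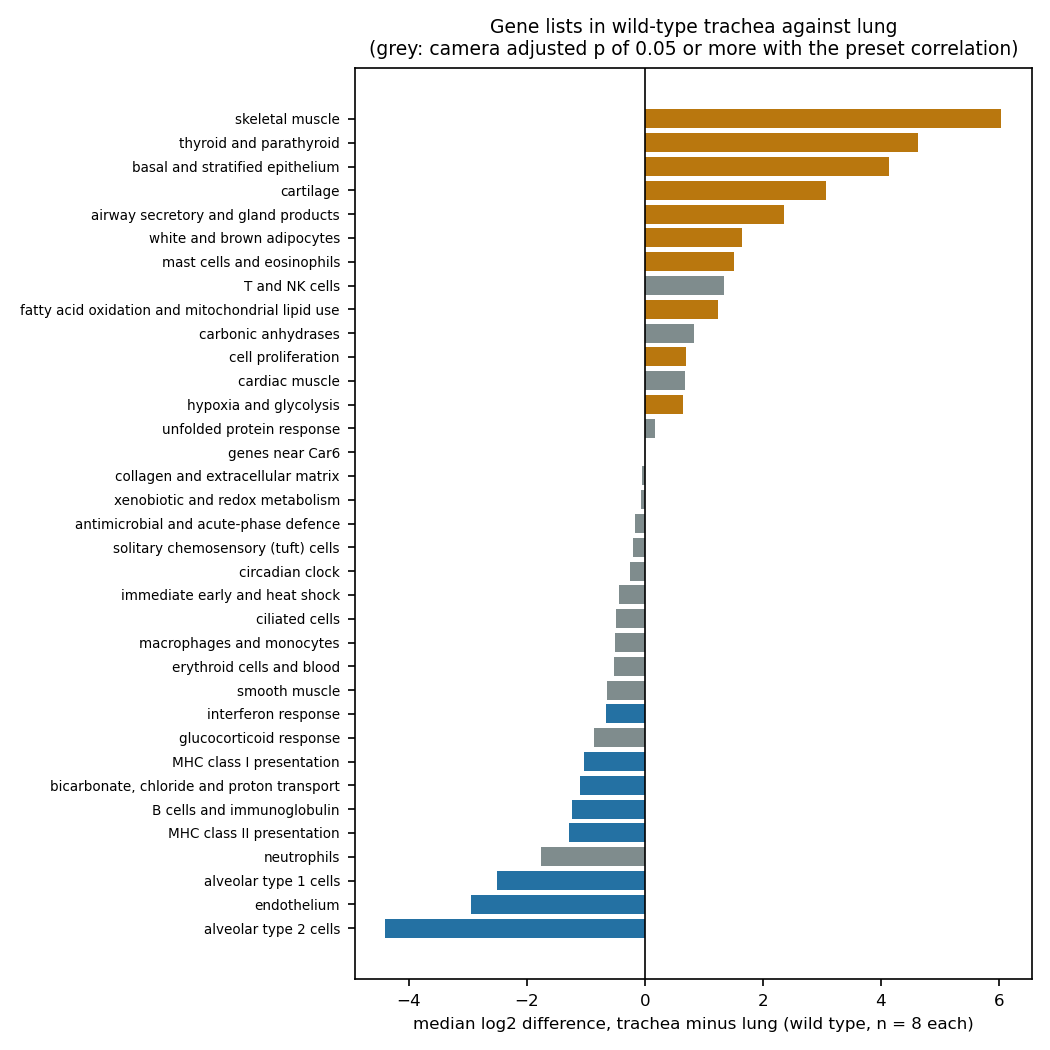
Median log2 difference of each gene list between wild-type trachea and lung (n = 8 each); positive bars are higher in trachea, and grey bars had a camera adjusted p of 0.05 or more with the preset correlation. Skeletal muscle (6.04) and alveolar type 2 genes (-4.40) stood at the ends.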

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

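The tests of Per3 alone, of the chromosome segment around Car6, of the tissue mix at genes near Car6 and of muscle genes in lung, the exact tests of list scores, the fit to genes detected in both tissues and the clock correlations within each genotype, were chosen only after the results they bear on had been seen. The 2 tests on the fixed list of genes near Car6 replaced a ratio in a window around Car6 and a correlation of its genes between tissues, both already run. Their bounds were set when the counts of 4 and 8 genes were known but not those of the splits. The condition on other clock genes in the test of Per3 was likewise set when their calls were known, in place of an exact test.

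In 10 of 138 groups of list scores and array measures (7.25%) 1 sample stood far from the rest of its group, measured as its gap to the nearest sample divided by the range of the group, where chance gives about 5%. Skeletal muscle genes were at 9.41 in Car6-/- lung 5, against 6.10 to 6.88 in the others (gap 0.764 of the range), and the unfolded protein response at 8.63 in Car6-/- lung 6, against 8.29 to 8.40 (0.668). Fatty acid oxidation was at 8.37 in wild-type lung 7, against 7.71 to 8.01 (0.544). Wild-type trachea 3 was highest for bicarbonate, chloride and proton transport (7.56 against 6.94 to 7.14, 0.669), erythroid genes (8.79 against 7.59 to 8.10, 0.572) and neutrophils (7.97 against 6.08 to 6.96, 0.533). Smooth muscle was at 8.28 in wild-type trachea 8, against 8.62 to 8.75 (0.721), and adipocytes at 9.20 in wild-type trachea 5, against 8.66 to 8.88 (0.584). Thyroid genes were at 9.19 in wild-type trachea 1, against 8.05 to 8.53 (0.581), and hypoxia at 9.66 in wild-type trachea 4, against 9.29 to 9.41 (0.668).

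Among the named genes, 20 of 280 groups (7.14%) held such a sample. In lung they were Car11 (5.57, gap 0.813) and Clock (8.56, 0.729) in Car6-/- lung 7, Agtrap (7.68, 0.740) in Car6-/- lung 2, Gsta4 (9.27, 0.538) in wild-type lung 1, Car14 (7.99, 0.682) in wild-type lung 3 and Cyp2e1 (10.37, 0.624) in wild-type lung 7. In Car6-/- trachea they were Krt6a (6.27, 0.906) and Tap2 (8.47, 0.726) in sample 4 and Nfil3 (8.90, 0.694) in sample 1. Wild-type trachea 3 stood apart for Angptl4 (9.47, 0.600), Art5 (6.94, 0.753) and Ube2l6 (6.98, 0.576). Wild-type trachea 4 did so for Casq1 (9.35, 0.560), Ckm (13.58, 0.571), Nfil3 (8.09, 0.761), Car14 (7.37, 0.540) and Car3 (12.28, 0.591). Arntl (5.31, 0.683) and Dnajc3 (9.36, 0.548) stood apart in wild-type trachea 5, and Slc25a20 (9.49, 0.571) in wild-type trachea 7.

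The genotype effect of 14 lists differed between trachea and lung by camera at its preset correlation, and 0 with an estimated correlation (adjusted p = 0.492 to 0.522). The median differences were 1.07 for adipocytes, -1.68 for skeletal muscle, 1.12 for B cells, -1.34 for thyroid, -0.62 for cartilage, -1.28 for basal epithelium and 0.72 for MHC class II. They were -0.33 for the unfolded protein response, 0.58 for fatty acid oxidation, 1.01 for alveolar type 2 cells, 0.37 for MHC class I, 0.23 for interferon, 0.66 for smooth muscle and 0.33 for macrophages. Thyroid, cartilage and basal epithelium had only 3 of 11, 4 of 15 and 1 of 19 members detected in lung, so their calls repeat the change in trachea and show no difference between tissues. Over genes detected in both tissues the other 11 kept their calls at the preset correlation and 0 with an estimated one. Exact permutation tests of the difference in scores, which leave out those 3 lists, gave an adjusted p of at least 0.168 for each list tested in both tissues. Chance could not be excluded for these 14 calls, since other splits of the samples called up to 22 lists, nor for the 9 lists in lung (up to 15) or the 17 in trachea (up to 23).

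The clock list was called in both tissues at the preset correlation, but no clock gene passed over all genes in either tissue alone. Arntl, Nfil3, Dbp, Usp2 and Nr1d2 were called for the average effect, which met the condition against Per3 alone, a gene near Car6. That model treats same-numbered lung and trachea as independent, although the clock score followed the number (r = 0.84), so these calls do not decide it. The score without Per3, formed after its genes had been seen, differed by 1.35 in lung. In trachea, Per3 was detected too rarely to be tested, while other clock genes passed when adjusted over the list alone. Per3 alone thus does not cover the shift in trachea. A candidate explanation is that several Car6-/- mice were collected at another phase of the daily cycle, which would shift both tissues of a mouse together. With genotype means removed, the clock scores of same-numbered lung and trachea correlated at r = 0.84 over 14 mice, which met the bound set before it was computed. The Car6-/- mice form separate clusters (1, 2, 4 and 5 against 6 and 7), so that their distance weighs on this value. Without Car6-/- mice 7 and 1 it was 0.77, with mouse 6 still apart from 2, 4 and 5. Within the 8 wild-type mice r was 0.45 (exact permutation p = 0.277) and rho 0.21 (exact permutation p = 0.619), and within the 6 Car6-/- mice r was 0.94 (exact permutation p = 0.00694) and rho 0.94 (exact permutation p = 0.0167), so this stays open under the wild-type condition added after the pooled value was seen. A different collection time and an effect of Car6 on the clock cannot be told apart, since no collection times are given in the sources used here and the design holds only 1 Car6-/- group.

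Genes near Car6 with the same direction in lung and trachea may reflect a chromosome segment that travelled with the targeted allele from another strain. In the list of genes near Car6 fixed before the data were examined, 4 of 39 genes had an unadjusted p under 0.05 and the same direction in both tissues. This share was 6.89 times that of other genes (121 of 8128). As to the count of 4, 3 of 100 splits of the mice, the real one included, gave the list as many (within the bound, which was set with the count known). The ratio itself was passed by other splits. It was 14.9 and 8.78 in the other splits with 4 list genes, which had 56 and 95 such genes elsewhere, and reached 78.2 in another split. An excess near Car6 relative to other genes is therefore not shown to be beyond chance. The tissue mix of the trachea samples is argued against as the whole cause, since 8 of 41 genes of this list passed in lung too when adjusted over the list alone, where no other split gave more than 3. Wild-type mice 1 and 2 lay at or near Car6-/- levels for some of these genes, such as Rbp7 in trachea (8.94 and 8.75, Car6-/- 8.93 to 9.85) and Agtrap in lung (8.76 and 8.49, Car6-/- 7.68 to 8.69), which a segment found only with the targeted allele would not give. In the other tissue they did not both stand apart from the other wild types. Rbp7 in lung was 6.23 and 6.38 (others 5.62 to 6.99), and Agtrap in trachea 8.30 and 8.04 (others 8.23 to 8.67). The segment and an untested effect of Car6 on its neighbours therefore stay open, since no genotypes of the flanking region were used here.

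Skeletal muscle, thyroid, basal epithelium and adipocyte lists were each called in trachea at the preset correlation (adjusted p = 0.516 to 0.558 with an estimated correlation), which may come from different amounts of surrounding tissue, but not in the same samples, since Car6-/- trachea 7 was low for thyroid (5.21) with muscle at 11.08 and basal epithelium at 9.32, and Car6-/- trachea 5 had basal epithelium at 7.57 with thyroid at 8.98. The spread of the muscle score within wild-type trachea was 0.205 of the genotype difference, between the bounds set beforehand for accepting and for excluding this explanation, while 91.7% of muscle genes and all thyroid and adipocyte genes moved in the direction of their list. The SD in Car6-/- trachea was 5.18 times that in wild type for muscle, 5.53 times for thyroid and 5.46 times for adipocytes, but 1.26 times for basal epithelium, where the wild-type SD of 1.36 exceeded the genotype difference of -1.28 in size (exact permutation p = 0.162) and wild-type trachea 1 and 5 lay at 6.51 and 6.84. An effect of the genotype on muscle genes in general would lower them in lung too, where the median change was -0.0385, but muscle scores in lung varied by an SD of 1.20 among Car6-/- samples, so this stays open. An effect of equal size in every Car6-/- mouse is argued against for thyroid, muscle and adipocyte genes. Car6-/- trachea 4 and 5 scored 8.63 and 8.98 for thyroid, within the wild-type range of 8.05 to 9.19. Their muscle scores were 11.27 and 11.14 (wild type 11.06 to 12.05). Their adipocyte scores were 8.60 and 8.85 (wild type 8.66 to 9.20). Beyond that, dissection and a genotype effect on these tissues cannot be told apart. The amount of surrounding tissue per sample is not given in the sources used here.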

How the results depend on the processing

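The average over both tissues, with and without a block, the exact permutation of list scores, the restriction to genes detected in both tissues and the settings that leave out several samples together were chosen after seeing the data. Of the 9 alternatives run for trachea against lung, 1 tested every detected probe and called 8743 of 13111 probes. Under the rest, the 6845 called genes became 6310 to 7364. With median scaling 2409 genes were higher and 4164 lower in trachea, against 2986 and 3859 in the main fit. The 2 genes called in lung became 5 without background correction and 5 with the authors' table, where Oas2 was no longer called (adjusted p = 0.0618 and 0.0501), 5 with trend and robust eBayes, 4 with the stricter detection filter and 6 with array weights. They became 0 with median scaling, with every probe tested, without second arrays, in 1 model of all 4 groups, with the replicate number as a block, and without Car6-/- lung 5 and wild-type lung 6 together, and 1 with cardiac muscle as a covariate. Leaving out single samples gave 0 to 44 genes in lung (44 without Car6-/- 7, 5 without Car6-/- 5, 4 without wild type 1 or 8, 1 without wild type 3, and 0 without Car6-/- 1, 2, 4 or 6 or wild type 4, 5, 6 or 7; the 2 genes without wild type 2 did not include Oas2) and 0 to 693 in trachea (693 without Car6-/- 4, and 1 without Car6-/- 5 or wild type 1). The 0 genes called in trachea became 1126 in 1 model of all 4 groups, which shares the smaller spread of lung, and 1 with the replicate block. The average effect over both tissues gave 106 genes, and 112 with the mouse number as a random block. The 0 genes for the difference between tissues became 73 with array weights. With an estimated correlation 0 lists were called in lung, trachea and for the difference, and exact permutation gave 0 in lung and trachea. Leaving out single samples gave 6 to 15 lists in lung (15 without Car6-/- 2) and 10 to 18 in trachea (10 without Car6-/- 1), and 12 without Car6-/- trachea 1, 2 and 6 together. Of the 17 lists in trachea, 7 kept their call and direction in this last setting, endothelium was called lower (median -0.118, adjusted p = 0.0434), B cells had too few detected genes and 8 were not called: basal epithelium (0.049, adjusted p = 0.532), alveolar type 2 cells (0.009, adjusted p = 0.849), the unfolded protein response (-0.055, adjusted p = 0.478), smooth muscle (adjusted p = 0.0908), erythroid genes (adjusted p = 0.268), interferon (adjusted p = 0.193), MHC class I (adjusted p = 0.165) and MHC class II (adjusted p = 0.242). Without Car6-/- lung 5 and wild-type lung 6 together, 7 of the 9 lung lists kept their calls, and glucocorticoid (adjusted p = 0.108) and xenobiotic genes (adjusted p = 0.107) did not. With 1 sample left out, the call of erythroid genes in trachea held in 4 of 14 fits (and in 4 of 7 planned settings), secretory products in 7, the unfolded protein response in 10, endothelium and the clock in 11, smooth muscle in 12 and alveolar type 2 cells in 13; in lung the clock held in 8, interferon and xenobiotic genes in 10, and MHC class II and glucocorticoid genes in 13. B cells in trachea could be tested in 9 and held in 9, and the other lists held in all 14. With the replicate number as a block, 7 of the 9 lung lists kept their calls, and MHC class II and xenobiotic genes did not. In trachea 16 of the 17 kept theirs. For the difference between tissues, 11 of 14 lists kept their calls over genes detected in both tissues, and thyroid, cartilage and basal epithelium had too few such genes. Except where the construction of the setting shows it, the cause was not tested. Of 1272 values of named genes under alternatives, 1199 kept direction and side of the threshold, 64 passed it newly, 8 no longer passed, and 1 reversed, Car4 in lung at 0.0567 with median scaling. Of 1941 values with 1 sample left out, 16 reversed, all in carbonic anhydrases that did not pass: Car3 (-0.693 to 0.199), Car4 (-0.0897 to 0.0258), Car13 (-0.165 to 0.0375) and Car14 (-0.153 to 0.0321) in lung, and Car14 (-0.0763 to 0.139) and Car2 (-0.217 to 0.00845) in trachea. With 1 sample left out, Oas2 in lung ranged from 0.47 to 0.56 and ILMN_2958159 from 0.51 to 0.59. The size of Oas2 depended on background correction. It was 0.21 without this correction and 0.24 with the authors' table, where ILMN_2958159 was 0.46 and 0.48. With median scaling they were 0.55 and 0.62. A chip block was not run, since no chip is given in the sources used here, the authors' table was not used between tissues, which it normalizes separately, and no setting gives a fold for Car6. Signal near background, with array medians of 92.4 to 118.3 over lowest signals of 65.7 to 82.7, limits weakly expressed genes.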

Other observations

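The average genotype effect over both tissues, its fit with the mouse number as a block, the genes named from it and the genes whose levels per sample follow were chosen only after the data had been seen; the comparison with other splits was planned. In 1 model of all 4 groups, limma called 106 of 10532 genes for this average, 68 higher and 38 lower in Car6-/- mice, with 1914 at an unadjusted p under 0.05. This model treats lung and trachea of 1 number as independent. With the mouse number as a random block 112 genes were called, including all 106, but the block uses 1 correlation for all genes (-0.02), which does not cover genes that follow the number more closely, such as those of the clock score (r = 0.84). The unnamed probe ILMN_2958159 had the smallest p (0.89 ± 0.12, adjusted p = 2.63e-04). Of the 106, 6 were genes of the clock score or Usp2, namely Arntl (1.03 ± 0.17), Nfil3 (0.97 ± 0.19), Dbp (-1.19 ± 0.25), Usp2 (-0.66 ± 0.13), Nr1d2 (-0.59 ± 0.14) and Per3, which was undetected in Car6-/- trachea. Single genes among the called ones were the chaperone genes Hsph1 (0.63 ± 0.15) and Hspa8 (0.22 ± 0.05), Chordc1 (0.59 ± 0.10), the cold-inducible RNA-binding protein gene Cirbp (-0.52 ± 0.11), Angptl4 (1.09 ± 0.19), the fatty acid elongase gene Elovl6 (0.68 ± 0.15), the citrate lyase gene Acly (0.57 ± 0.14), the interferon-induced genes Oas2 (0.54 ± 0.12) and Bst2 (0.54 ± 0.13) and the elastin gene Eln (0.66 ± 0.15). No gene list was tested for the average effect.

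In the window of 100 genes on each side of Car6, 5 of 83 genes were called for the average effect (6.02%), compared with 91 of 9614 elsewhere (0.947%). The window was chosen after several of these genes had been seen to differ in both tissues, so no test is given. They included Rbp7 (1.02 ± 0.17), Clstn1 (-0.85 ± 0.15), Agtrap (-0.59 ± 0.11) and Plod1 (0.42 ± 0.10).

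Wild-type mice 1 and 2 stood apart from the other wild-type mice for some of 5 genes with a low p for genotype, not always in both tissues. For Rab6b they measured 6.56 and 6.74 in lung, where wild types 3 to 8 measured 8.38 to 8.75 and Car6-/- mice 6.01 to 6.92. In trachea they measured 4.67 and 4.89, the others 5.68 to 7.17 and Car6-/- mice 4.45 to 6.38, with detection in 6 of 8 wild-type and 2 of 6 Car6-/- trachea samples. For Rbp7 in trachea they measured 8.94 and 8.75, the other wild types 7.41 to 8.08 and Car6-/- mice 8.93 to 9.85. For Agtrap in lung they measured 8.76 and 8.49, the other wild types 9.09 to 9.46 and Car6-/- mice 7.68 to 8.69. For Clstn1 in lung they measured 6.99 and 7.09, the other wild types 7.45 to 8.00 and Car6-/- mice 5.76 to 7.08. For Miip in trachea they measured 5.89 and 5.95, the other wild types 6.23 to 6.75 and Car6-/- mice 5.53 to 6.64. They did not both stand apart for Clstn1 in trachea (6.60 and 6.51, others 6.35 to 6.94), Rbp7 in lung (6.23 and 6.38, others 5.62 to 6.99), Agtrap in trachea (8.30 and 8.04, others 8.23 to 8.67) or Miip in lung (6.24 and 6.43, others 6.36 to 6.74). No explanation was tested.

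Other splits of the samples into groups of these sizes, 100 drawn with the real one included, were compared with the real counts. For the 2 genes called in lung the highest count of another split was 1, and only 1 split, the real one, reached 2. This met the bound set beforehand for the count. With counts this small, and calls that ended under several settings given above, chance is not excluded for the 2 genes. For the 6845 genes between trachea and lung chance was excluded (highest other 4993, and 1 split as large). For the 106 genes of the average effect 4 splits were as large, the real one included, narrowly within the bound at 0.05. Since 3 other splits called over 100 genes, up to 536, chance is not excluded for these genes. The cause of the large counts in other splits was not tested. For trachea and for the difference between tissues the real count was 0, which each of the 100 splits reaches by construction, so that the comparison says nothing on chance there. Other splits called up to 993 and 156 genes, and the cause of these counts was not tested either. For lists, 30 splits gave as many as the 9 in lung, 13 as many as the 17 in trachea and 27 as many as the 14 for the difference between tissues.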
